A study of Homo sapiens with 4 samples.

How the data were processed

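Gene expression was measured in HepG2, a human liver cancer cell line, grown in 3-dimensional dextran hydrogels and collected after 24 h, per the labels' protocols. The labels give 2 samples cultured without added pressure (control 1 and 2) and 2 samples placed in a Flexcell compression plate at 1.995 kPa, or 15 mmHg (pressure 1 and 2). A line of the labels' treatment protocol names 30 mmHg in place of 15 mmHg, and nothing in the sources used here settles which was applied. Nothing in the labels says whether the samples of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical.

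Each sample was hybridised to 1 single-colour (Cy3) Agilent array with probes for mRNAs and long non-coding RNAs. The deposited intensity values of each spot were made with Agilent Feature Extraction 10.7.1.1, per the file headers, which record spatial detrending, no subtraction of the local background, multiplicative detrending and surrogate values for spots near background. These processed intensities were not normalized between arrays, per the file headers. Each array held 62976 spots, of which 60901 were gene spots for 58201 probes. Each spot also carries flags for saturation, outliers and signal well above background. No spot was saturated. The deposited series table holds log2 values. It correlated with log2 of the scanner's processed intensities at r = 0.9999 to 1.000 across probes, and its sorted values differed between arrays by at most 0.000917, as after quantile normalization between arrays. Every column of it had a median of 4.07. The tool behind that normalization is not given in the sources used here.

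Between 48.1% and 50% of probes were well above background on an array. The 75th percentile of the processed signal lay between 235 and 270. The arrays shared 1 slide and 1 scan. Control 1 lay in slide row 1 and the other arrays in slide row 2. Of 10 spike-in probes, the 7 brightest differed by at most 0.156 in unscaled log2 signal between the group means.

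Control spots and outlier-flagged spots were left out, and log2 processed intensities were averaged over the spots of a probe. Each array's 75th percentile over all gene probes was then subtracted. A probe was kept where it was well above background on both arrays of at least 1 group. Where several probes of a gene were kept, the probe with the highest mean over the 4 arrays stood for the gene, and a probe with no gene name was tested on its own. Names came from a RefSeq table through accessions, symbols or unique synonyms for 34966 probes. A further 21728 probes kept the name in the files and 1507 had none. Genes with a missing value on an array, 9 in all, were left out. This left 23091 genes, 16562 of them with a reference symbol. Probe coordinates are those of the array files, on build hg19 (GRCh37). No genome sequence was used, so the exon or UTR under a probe is not given.

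Groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with the group as the only term and a two-sided moderated test. Adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05. The residual degrees of freedom were 2 and the prior degrees of freedom 1.54. Differences are log2 values, pressure minus control. A gene whose tested probe was not well above background on either array of a group has only a bound there. For such a gene the mean of the brighter group was set against the mean, over the dim group's arrays, of the higher of the probe's own value and the lowest signal well above background on that array. The ratio is written as "at least N-fold". It is also given for named genes with 1 of 2 arrays of the lower group well above background. Levels of different probes were not set against each other, except as percentiles of hepatocyte genes among the tested genes' group means.

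There were 30 gene lists, chosen before the data were examined, and each with at least 5 tested members was tested with limma's camera at a preset correlation of 0.01. Camera with an estimated correlation and fry were alternatives. With an estimated correlation camera uses the 2 residual degrees of freedom, so few lists can pass with so few arrays. Calls within a list were also adjusted over the list alone. Genes named in the text follow a rule chosen before the data were examined. It takes the 12 largest rises and 12 largest falls by log2 difference, dim signals included. These are among genes with an approved symbol past the threshold and well above background on both arrays of the higher group. It adds up to 2 rises and 2 falls from each list, or the 2 largest differences where none passes, the genes ACTB, GAPDH, B2M, TBP, HPRT1 and PPIA, and PIEZO1. Some genes that the rule takes are not reported here. Other genes named were chosen after their values were seen and serve as examples.

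Alternatives covered the background correction (normexp with offset 50), quantile and median scaling, the filter on dim probes, single probes in place of genes, the series table, an intensity trend, a replicate block, each array left out in turn and other thresholds. The median log2 difference of all genes was -0.05, and median scaling moved it by 0.10, so differences of that size have no settled direction. The fit was tested on simulated data for this comparison with 23091 genes, 2 arrays per group and 200 changed genes. It recovered 40% of 100 genes changed 2-fold and 76% of 100 genes changed 4-fold, none in the wrong direction, and called 3 unchanged genes. In the real arrays 69.6% of genes passed, a far larger share, so these figures do not give the recovery or false calls there. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The number of arrays limits the precision.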

Results

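Expression was compared between 2 arrays labelled control and 2 arrays labelled pressure-treated (15 mmHg for 24 h), all labelled as HepG2 cells in 3-dimensional hydrogel culture. Each array measured mRNAs and long non-coding RNAs with 58201 gene probes, of which 48.1% to 50% were well above background. The series' title gives the purpose as finding transcripts involved in proliferation and invasion under mechanical pressure. HepG2 is a liver cancer line known for secreting plasma proteins such as albumin.

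The groups differed across most of the transcriptome while arrays within a group were close to copies of each other. Across the 23091 tested genes, which are not independent replicates, Pearson r was 0.996 between the control arrays and 0.996 between the pressure-treated arrays. Between arrays of different groups it was 0.804 to 0.807. Spearman's rho was 0.995 to 0.996 within groups and 0.816 to 0.818 between them. The SD of log2 differences between arrays was 0.315 within control, 0.303 within pressure-treated and 2.07 to 2.09 across groups. The first principal component held 97.8% of the variance and separated the groups.

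**Figure D1:**
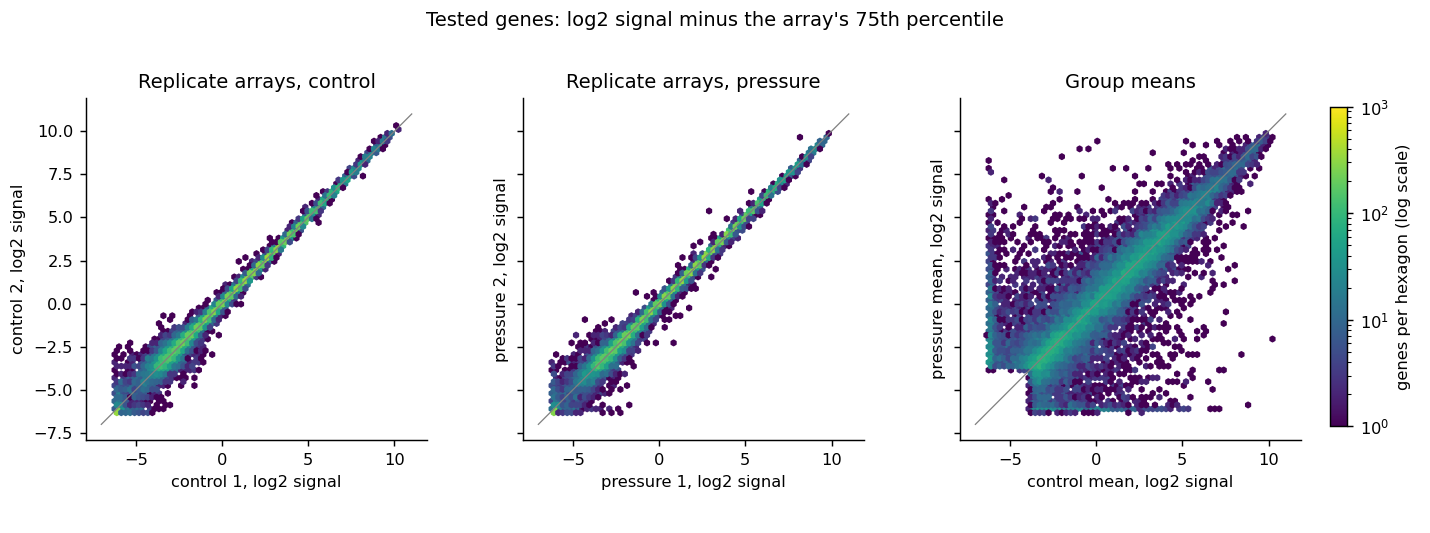
Each panel plots log2 signal minus the array's 75th percentile for the tested genes, with hexagons coloured by the number of genes on a log scale and the diagonal in grey. The replicate panels (r = 0.996 in each) lie along the diagonal, while the group means spread away from it in both directions, with many genes at the background level of 1 group.

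Of the 23091 genes, 16076 (69.6%) passed an adjusted p of 0.05, with 7634 higher and 8442 lower in the pressure-treated arrays. Which direction held more genes depended on the scaling, with 8481 higher and 7543 lower under median scaling. A difference of at least 2-fold with no overlap between the groups' arrays was seen in 8218 genes, 4119 higher and 4099 lower. That count was 5205 with normexp background correction and 4988 over probes well above background on all 4 arrays. Arrays of the groups did not overlap in 85.9% of genes, where chance gives 33.3%. Among genes with a reference symbol, 922 were well above background on both pressure-treated arrays and on neither control array, and 943 showed the opposite. At least 100-fold separated the groups in 138 genes that were higher and 107 that were lower in the pressure-treated arrays. Groups are named by their labels throughout. The count of genes past the threshold was 8094 at an unadjusted p under 0.05 with a 2-fold difference, and 5961 when the test was made against a 2-fold difference.

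Genes that define the hepatocyte, the plasma-protein-secreting cell of the liver, were mostly not well above background in the control arrays. Of 20 secreted proteins in the list, 5 were well above background on both control arrays, 17 on both pressure-treated arrays and 2 (APOA2 and APOC3) on none. Detection on the pressure-treated arrays did not always mean a high level. By percentile among the tested genes' mean signals there, APOH stood at 90, RBP4 at 86.4, ALB at 63.3, APOB at 24.9 and SERPINA1 at 20.7. Albumin (ALB) had a log2 signal of -6.05 ± 0.15 (SD, n = 2) in control, not well above background, and 1.58 ± 0.03 (SD, n = 2) in pressure-treated arrays. Alpha-fetoprotein (AFP) was not well above background in control (-4.45 ± 0.05) and stood at 2.00 ± 0.07 in pressure-treated arrays. APOH, a phospholipid-binding plasma protein, was at least 439-fold higher in the pressure-treated arrays, and the liver transcription factor FOXA2 at least 407-fold higher (limma adjusted p = 2.84e-05 for each). ONECUT1, also a liver transcription factor, was not well above background on the control arrays. APOA1, the main protein of high-density lipoprotein, differed the other way by 1.23-fold (log2 -0.30, SE 0.05, adjusted p = 0.0122), a call lost without any 1 of the 4 arrays (adjusted p 0.0502 to 0.0681), with the intensity trend (0.0923) and without the filter on dim probes (0.0577).

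In the whole hepatocyte list, 19 of 25 tested members were higher in the pressure-treated arrays, 1 was lower and 5 did not pass, and 20 passed when adjusted over the list alone. The list's median log2 difference was 4.70, or 2.97 with dim members at their bound. Camera gave an adjusted p of 1.14e-05, and 0.505 with an estimated correlation. Over probes well above background on all 4 arrays the list did not pass (adjusted p = 0.387), since its dim members then left the test, while over all 13 refits at the preset correlation the adjusted p ranged from 5.1e-09 to that value.

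**Figure D2:**
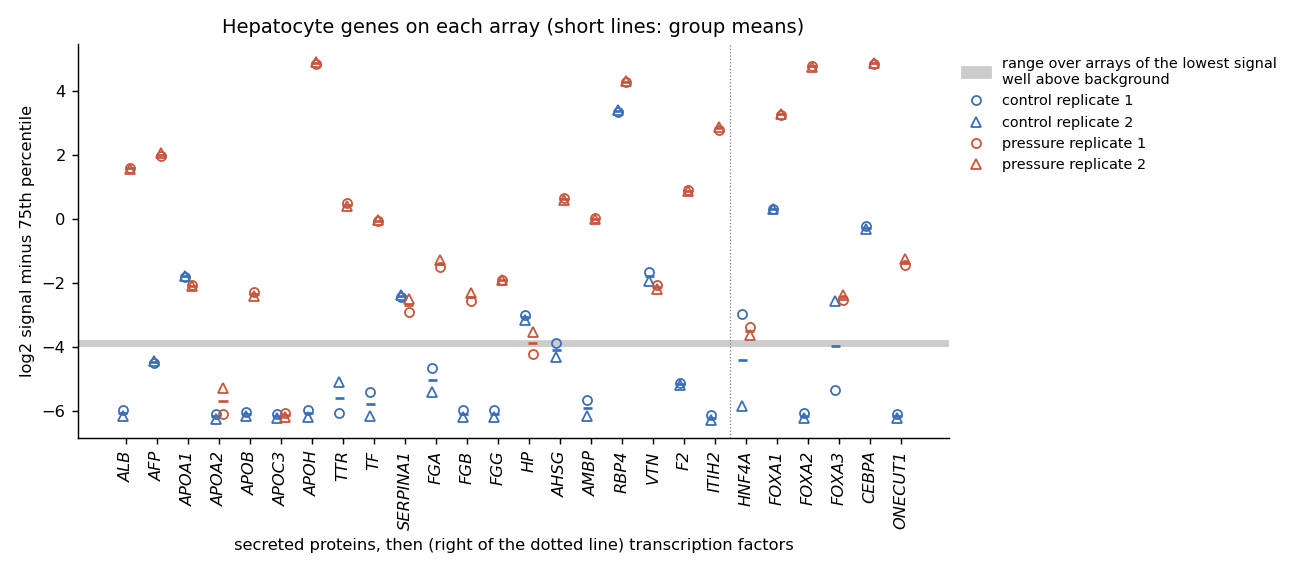
Log2 signal minus the array's 75th percentile for 26 hepatocyte genes on each of the 4 arrays, with short lines at the group means (n = 2) and a grey band for the lowest signal well above background. ALB, AFP and APOB lie below the band on the control arrays and above it on the pressure-treated arrays, while APOA2 and APOC3 lie below it on every array.

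Genes of bile acid and xenobiotic metabolism followed a similar split. Of 16 tested members, 13 were higher in the pressure-treated arrays, 1 was lower and 2 did not pass (14 passed adjusted over the list alone). UGT2B7, which glucuronidates steroids and drugs, was at least 498-fold higher. Another of its probes differed by 6.99 log2 units, from control signals that were also not well above background. CYP27A1, a sterol hydroxylase of bile acid synthesis, was 378-fold higher (log2 8.56, SE 0.07). CYP1A1, the aryl hydrocarbon-induced cytochrome, was 2.07-fold lower. The median was 3.74 (3.08 with bounds) and camera's adjusted p was 6.94e-05, against 0.505 with an estimated correlation. These genes moved with the hepatocyte secreted proteins, of which 5 of 20 were well above background on both control arrays.

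The 12 largest rises by log2 difference were genes that were not well above background on the control arrays. Dim signals enter that ranking, so it does not order the bounds. KRT19, not among the 12, was 903-fold higher, above the lowest bounds below. UCHL1, a neuronal deubiquitinase also made by tumours, had a log2 signal of -6.17 ± 0.09 (SD, n = 2) in control and 8.39 ± 0.01 in pressure-treated arrays, at least 5015-fold apart (adjusted p = 2.84e-05; probe on chromosome 4, 41270340 to 41270399, hg19). AGR2, a protein disulfide isomerase of secretory epithelia, was at least 3636-fold higher (chromosome 7, 16837274 to 16839382, a span that the probe covers in parts). CEACAM6, a cell adhesion molecule, and ALDH1A1, a retinaldehyde dehydrogenase, were at least 2866-fold and 2816-fold higher. Another ALDH1A1 probe was well above background on 1 control array and 7.13 log2 units higher. SPANXA1, a testis gene whose near-identical copies share probes, was at least 2080-fold higher. SPP1 (osteopontin), KRT20 (an intestinal keratin), IL13RA2, LAD1, NR0B1, CMTM7 and BCAS1 were at least 616-fold to 988-fold higher. Another NR0B1 probe was 4.05 and another CMTM7 probe 5.54 log2 units higher, each from control signals that were also not well above background. The adjusted p of these 12 genes lay between 2.84e-05 and 0.000267.

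The 12 largest falls by log2 difference were bright on the control arrays. Dim signals enter that ranking, so it does not order the bounds. FSTL1, not among the 12, was at least 1287-fold lower, above the lowest bounds below. LY6K, a testis and tumour surface protein, had a log2 signal of 8.82 ± 0.005 (SD, n = 2) in control and -5.76 ± 0.65, not well above background, in pressure-treated arrays, at least 6626-fold apart (adjusted p = 9.26e-05; chromosome 8, 143784821 to 143784880, hg19). SPINK6, a protease inhibitor, IGFBP7, a secreted binding protein, and GAL (galanin) were at least 2002-fold, 1737-fold and 1549-fold lower. The other IGFBP7 probes differed by -13.04 and -4.52, and were also not well above background on the pressure-treated arrays. FOLR1, the folate receptor alpha, fell by 12.15 log2 units (SE 0.31) from 10.21 ± 0.04 (SD, n = 2) to -1.94 ± 0.57. BASP1 was 2765-fold lower, and PYCR1, a proline synthesis enzyme, at least 2152-fold lower with 1 of 2 pressure-treated arrays well above background and a difference of -6.65 by another probe. LINC00473, PXDN, CXCR4 (a chemokine receptor), FOLR3 and RNF182 were at least 508-fold to 630-fold lower. The other LINC00473 probes differed by -8.96 and -7.20, and were likewise not well above background on those arrays. The adjusted p of these 12 genes lay between 2.84e-05 and 0.000379.

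Targets of NRF2, the transcription factor of the antioxidant response, were higher in the pressure-treated arrays. Of 19 tested members, 16 were higher, none was lower and 3 did not pass, and 16 passed when adjusted over the list alone. AKR1B10, an aldo-keto reductase, was 634-fold higher (log2 9.31, SE 0.06, adjusted p = 2.84e-05). HMOX1, NQO1 and TXNRD1 were 7.39-fold, 7.97-fold and 5.90-fold higher. The median was 2.15 and camera's adjusted p 5.84e-06, the lowest of the 30 lists, against 0.505 with an estimated correlation. The correlation estimated for this list was -0.04, below the preset 0.01, so the higher p does not come from correlated members.

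Genes of cell division were lower in the pressure-treated arrays. In the mitosis list, 26 of 28 members were lower, 1 was higher and 1 did not pass (27 passed adjusted over the list alone), with a median of -0.89. CDK1, the mitotic kinase, was 2.97-fold lower (log2 -1.57, SE 0.05, adjusted p = 0.000202), and KIF2C, a microtubule depolymerase, 2.87-fold lower. MKI67, the common proliferation marker, was at -0.30 and did not pass (adjusted p = 0.137). NDC80, a kinetochore protein, was 1.21-fold higher, a call lost without any 1 array (adjusted p 0.0581 to 0.0933), with the replicate block (0.0560) and without the filter (0.0799). Camera's adjusted p for the list was 1.14e-05, and 0.505 with an estimated correlation. Replication-dependent histones went the same way, with 12 of 14 lower, none higher and 2 not passing (12 adjusted over the list alone), a median of -1.17, and H2AC8 (6.88-fold) and H1-2 (4.02-fold) the furthest apart. Their camera adjusted p was 0.000669 and, with an estimated correlation, 0.505. Near-identical histone copies can share a probe.

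The list of DNA replication and the G1/S transition did not move as one. It held 5 higher, 12 lower and 9 not passing among 26 (17 adjusted over the list alone; camera adjusted p = 0.321). GINS1 and PCNA were 2.57-fold and 1.55-fold higher, POLA1 and RRM2 3.79-fold and 2.66-fold lower, though the other RRM2 probes differed by -6.91 and -2.55 log2 units. Cytosolic ribosomal proteins were lower in 22 of 33 members and higher in 5, with 6 not passing (27 adjusted over the list alone) and a median of -0.37. RPL37 and RPS3 were 2.22-fold and 1.94-fold lower. RPL18 was 1.21-fold higher, a call lost without any 1 array (adjusted p 0.0565 to 0.0825), with the replicate block (0.0552) and without the filter (0.0707). Camera's adjusted p for the ribosomal list was 0.0204, against 0.678 with an estimated correlation, 0.212 after quantile normalization, 0.210 with the series table and 0.0532 without pressure replicate 2. Over 13 refits it ranged from 0.00241 to 0.212.

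The list of metallothioneins, small metal-binding proteins, and zinc export was lower in the pressure-treated arrays. Of 9 tested members (8 metallothioneins and the zinc exporter SLC30A1), 8 were lower, none was higher and 1 (MT1G) did not pass (8 adjusted over the list alone). MT1M was at least 174-fold lower and MT1E 54.4-fold lower (log2 -5.77, SE 0.06), with other MT1E probes between -10.22 and -5.56. MT2A was 15.3-fold lower. The median was -3.93 and camera's adjusted p 0.000678, against 0.505 with an estimated correlation. Metallothioneins are similar enough in sequence that probes can share signal.

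Epithelial junction and keratin genes were mostly higher in the pressure-treated arrays, with 17 of 23 higher, 4 lower and 2 not passing (21 adjusted over the list alone). KRT19, a simple-epithelium keratin, was 903-fold higher (log2 9.82, SE 0.07). CDH1 (E-cadherin) was not well above background in control and at least 28.4-fold higher. EPCAM, an epithelial adhesion molecule, was 10.1-fold lower and JUP (plakoglobin) 3.25-fold lower. The median was 1.26, or 0.73 with bounds, and camera's adjusted p 0.00364, against 0.505 with an estimated correlation. Mesenchymal genes split, with 10 higher, 8 lower and 3 not passing among 21 (20 adjusted over the list alone; camera adjusted p = 0.573), a median of 0.27 and a mean of -0.10. FN1 (fibronectin) was at least 114-fold higher and LOXL1, a collagen cross-linking enzyme, 6.00-fold higher. FSTL1 was at least 1287-fold lower and TWIST1, a mesenchymal transcription factor, at least 15.7-fold lower.

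Matrix proteases, which the invasion question concerns, were higher in 16 of 25 members, lower in 7 and did not pass in 2 (23 adjusted over the list alone). The metalloproteinases MMP7 and MMP1 were 312-fold and 265-fold higher. ADAMTS1 and MMP15 were 4.89-fold and 2.54-fold lower. The median was 0.94 and camera's adjusted p 0.0284, against 0.505 with an estimated correlation and 0.0571 over probes well above background on all 4 arrays (0.00407 to 0.0571 over 13 refits). Integrin, focal adhesion and actin genes held 17 higher, 9 lower and 6 not passing among 32 (27 adjusted over the list alone; camera adjusted p = 0.20). ITGAV and ITGA6 were 4.79-fold and 3.04-fold higher. MYL9, a myosin light chain, was 36.5-fold lower and RHOB 4.39-fold lower.

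In the list of mechanosensitive channels and caveolae, 11 of 16 members were higher in the pressure-treated arrays, 2 lower and 3 did not pass (14 adjusted over the list alone). The cation channel TRPV2 was 96.1-fold higher (log2 6.59, SE 0.08) and CAV2 (caveolin-2) 49.1-fold higher. TRPM7 was 1.46-fold lower, and TRPC6 1.29-fold lower, a call lost without pressure replicate 1 (adjusted p = 0.0579) or pressure replicate 2 (0.0545). PIEZO1, a stretch-gated channel, had a log2 signal of 6.71 ± 0.03 (SD, n = 2) in control and 7.30 ± 0.01 in pressure-treated arrays, 1.5-fold higher (adjusted p = 0.00194), but its other probe differed by -0.44, in the opposite direction. The list's median was 0.97 and camera's adjusted p 0.0105, against 0.589 with an estimated correlation. Targets of YAP and TAZ, the transcription coactivators of the Hippo pathway, were higher in 6, lower in 13 and did not pass in 2 of 21 (19 adjusted over the list alone; camera adjusted p = 0.0959). Their median was -1.22, or -0.79 with bounds. TGFB2 and ASAP1 were 6.96-fold and 2.17-fold higher, FOXF2 and ARHGEF17 at least 141-fold and 175-fold lower. Without the filter on dim probes this list passed (adjusted p = 0.0207, with 0.0207 to 0.338 over 13 refits). Immediate early genes held 10 higher, 8 lower and 6 not passing among 24 (18 adjusted over the list alone; camera adjusted p = 0.741), with a median of -0.02 and a mean of 0.30. EGR2 was at least 7.36-fold higher and DUSP6 18.3-fold higher, NR4A3 40.6-fold and NR4A2 7.02-fold lower.

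Genes of NF-kappaB signalling, cytokines and the acute phase were higher in 17, lower in 5 and did not pass in 3 of 25 (23 adjusted over the list alone). The chemokine CCL20 was at least 63.5-fold higher and LCN2 (lipocalin-2) 80.2-fold higher, while CCL2 was at least 43.5-fold lower and complement C3 12.5-fold lower. The median was 0.97 and camera's adjusted p 0.0156, against 0.505 with an estimated correlation, which was -0.02 for this list, below the preset 0.01. Interferon-response genes held 11 higher, 8 lower and 2 not passing among 21 (19 adjusted over the list alone; camera adjusted p = 0.335). IFI27 was at least 32.3-fold higher, and OAS2 at least 97.5-fold higher by its tested probe. Its other probes, 1 of them well above background on 1 control array, differed by 3.00 and 3.42 log2 units. IFIT1 was 10.8-fold lower. Targets of p53 held 8 higher, 10 lower and 4 not passing among 22 (18 adjusted over the list alone; camera adjusted p = 0.767). TP53INP1 was at least 15.0-fold (2.75 log2 units by another probe) and BAX 3.40-fold higher, the death receptor FAS at least 85.9-fold and PHLDA3 49.5-fold lower. That other TP53INP1 probe was also not well above background in control. Wnt targets held 9 higher, 3 lower and 4 not passing among 16 (12 adjusted over the list alone; camera adjusted p = 0.0674, and 0.0275 without the filter on dim probes, with 0.0275 to 0.230 over 13 refits). RNF43 and AXIN2, feedback inhibitors of the pathway, were 163-fold and 53-fold higher, LEF1 and SP5 44.3-fold and 7.78-fold lower.

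Lists of hypoxia, glycolysis, lipids and oxidative phosphorylation held members in both directions and did not pass camera. Hypoxia genes held 9 higher, 11 lower and 5 not passing among 25 (20 adjusted over the list alone; camera adjusted p = 0.533), with CA12 6.58-fold and PFKFB3 2.39-fold higher, AK4 26.5-fold (other probes -4.64 and -3.12 log2 units) and EGLN3 at least 1.71-fold lower. Glycolysis held 6 higher, 6 lower and 4 not passing among 16 (12 adjusted over the list alone; adjusted p = 0.993), with a median of 0.05 and a mean of -0.56. ENO2 and PKM were 1.72-fold and 1.71-fold higher, and HK2, a hexokinase of many tumours, 169-fold lower, with ALDOC 6.25-fold lower. Cholesterol synthesis and uptake genes held 10 higher, 8 lower and 6 not passing among 24 (18 adjusted over the list alone; adjusted p = 0.998), with a median of 0.04 and a mean of -0.27. TM7SF2 was 2.06-fold higher and INSIG1 3.59-fold lower. Fatty acid synthesis and lipid droplet genes held 9 higher, 6 lower and 4 not passing among 19 (16 adjusted over the list alone; adjusted p = 0.533), with PLIN4 33.3-fold and ELOVL6 8.26-fold higher, PNPLA3 8.44-fold and FADS1 2.35-fold lower. Oxidative phosphorylation held 6 higher, 14 lower and 7 not passing among 27 (20 adjusted over the list alone; adjusted p = 0.321), with UQCRFS1 2.15-fold and NDUFA1 1.98-fold higher, SDHA 2.46-fold and NDUFS3 2.37-fold lower.

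The folding branch of the ER stress response held 11 higher, 5 lower and 2 not passing among 18 (16 adjusted over the list alone; camera adjusted p = 0.204). EDEM1 and DNAJB9 were 2.77-fold and 2.40-fold higher, PDIA6 and HERPUD1 2.19-fold and 1.65-fold lower. ATF4 and amino acid stress genes held 7 higher, 12 lower and 5 not passing among 24 (20 adjusted over the list alone; adjusted p = 0.390). ATF5 and DDIT3 were 5.35-fold and 3.87-fold higher, DDIT4 and the serine synthesis enzyme PHGDH 8.24-fold and 7.25-fold lower. Heat shock genes held 6 higher, 8 lower and 4 not passing among 18 (14 adjusted over the list alone; adjusted p = 0.993). DNAJB1 and BAG3 were 2.10-fold and 1.90-fold higher, HSPA6 and HSPA1L 4.58-fold and 2.96-fold lower.

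Markers of other cell types also moved in both directions. Fibroblast and stellate cell markers held 2 higher and 6 lower among 8 (8 adjusted over the list alone; camera adjusted p = 0.321), with a median of -2.17 or -1.02 with bounds, and fry pointed upward. LUM (lumican) was at least 134-fold and COL6A3 at least 2.56-fold higher, COL5A1 186-fold and ACTA2 at least 8.75-fold lower. The other COL5A1 probes differed by -5.79 and -0.60 log2 units. Endothelial markers held 3 higher, 1 lower and 2 not passing among 6 (4 adjusted over the list alone; adjusted p = 0.501), with a median of 1.19 or 0.03 with bounds. PECAM1 was at least 32.6-fold and KDR at least 19.1-fold higher, ESAM 2.64-fold lower. Leukocyte markers held 2 higher, 4 lower and 4 not passing among 10 (6 adjusted over the list alone; adjusted p = 0.838), with a median of -0.31, and fry pointed upward. ITGAM was at least 26.2-fold and CD79A 1.68-fold higher. CSF1R was at least 3.03-fold lower, a call lost without control replicate 1 (adjusted p = 0.0677) or control replicate 2 (0.0639).

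**Figure D3:**
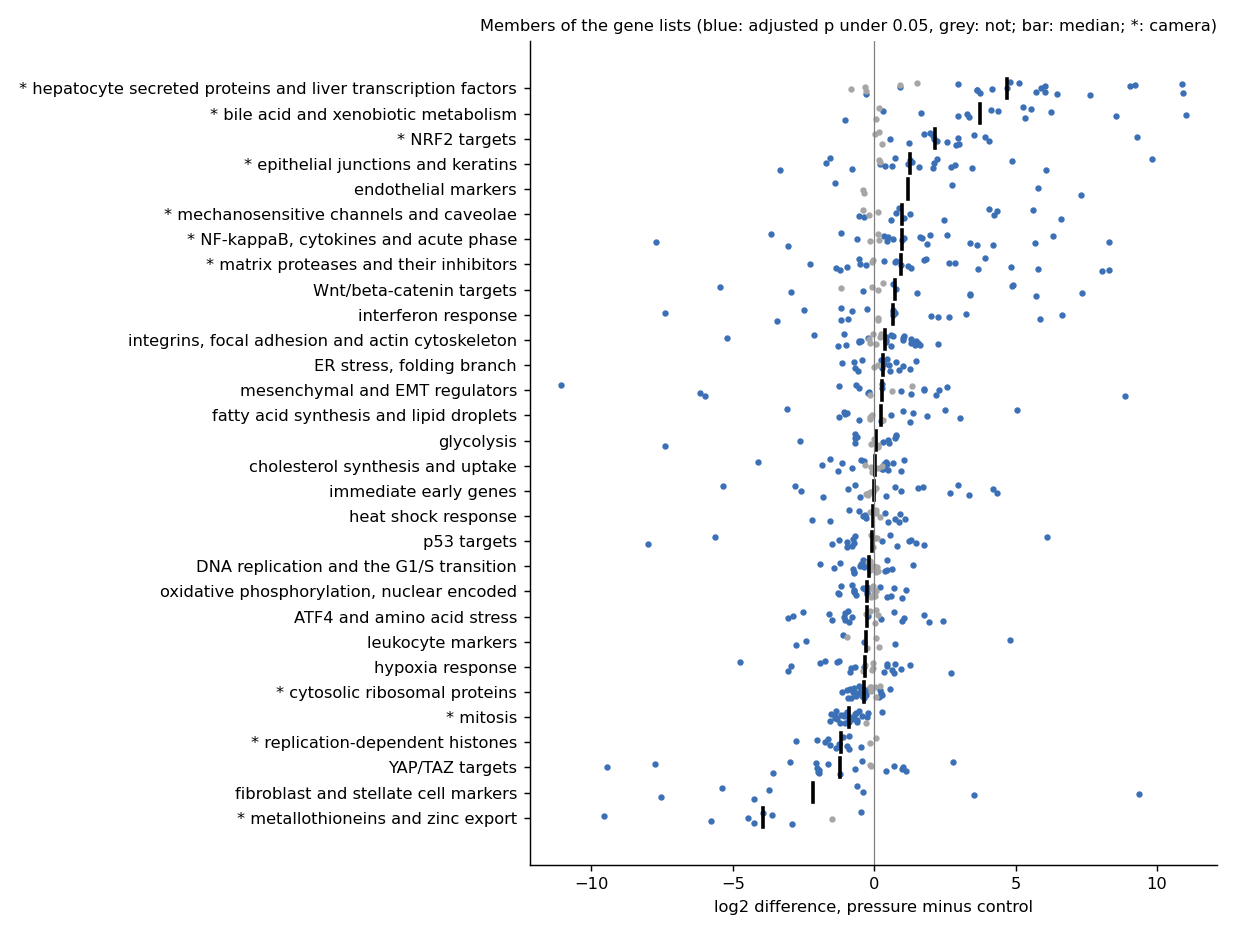
Log2 difference (pressure minus control, 2 arrays per group) of each tested member of the 30 lists, with black bars at list medians and asterisks on lists past camera's adjusted p of 0.05 at the preset correlation. NRF2 targets lie to the right of 0 (median 2.15) and mitosis genes mostly to the left (median -0.89), while glycolysis genes lie on both sides (median 0.05).

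In all, 11 of the 30 lists passed camera at the preset correlation, 7 higher and 4 lower. With an estimated correlation 0 passed, and 1 list had an unadjusted p under 0.05. That setting rests on 2 residual degrees of freedom, so it does not show that correlated members undid the calls. By fry, which asks only whether a list's genes move on balance one way, 28 passed.

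Widely used reference genes differed little. ACTB was at 9.59 ± 0.03 (SD, n = 2) in control and 9.41 ± 0.05 in pressure-treated arrays (limma adjusted p = 0.0656), GAPDH at 8.66 ± 0.05 and 8.64 ± 0.04 (adjusted p = 0.780), and TBP at 1.27 ± 0.03 and 1.42 ± 0.03 (adjusted p = 0.0811). The sign of the GAPDH difference changed to 0.08 with median scaling and 0.13 with quantile normalization, and that of ACTB to 0.01 with quantile normalization. B2M was 1.18-fold lower (adjusted p = 0.0285) and HPRT1 1.18-fold higher (adjusted p = 0.0276), both calls lost without any 1 array (adjusted p 0.0763 to 0.124 for B2M and 0.0639 to 0.121 for HPRT1) and with the replicate block (0.0690 and 0.0779) and without the filter (0.111 and 0.105), and B2M also with median scaling (0.124). PPIA was 1.29-fold lower (adjusted p = 0.0143), lost without control replicate 2 (0.0652), pressure replicate 2 (0.0646) or the filter (0.0510). ACTB passed with the intensity trend (0.0244) and with the 75th percentile over probes well above background (0.0464), and TBP with that trend (0.0475) and with median scaling (0.0278).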

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

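The 75th percentile over probes well above background and the test against a 2-fold difference were chosen after seeing the data. None of the named genes or lists that passed changed direction under the alternatives run, in which each gene was read from 1 probe, but another PIEZO1 probe differed by -0.44 against 0.59. Over named genes, 1884 values kept their side of the threshold, 38 lost a call and 4 gained one. Over lists, 381 kept it, 5 lost a call and 2 gained one. The count of genes past the threshold (16076) stayed between 13157 and 16853 across background, scaling, filter, series table and trend settings, and was 13882 to 14547 with 1 array left out, where a lone array is assumed to vary like the other group. The filter also changed how many genes were tested. Of 18946 genes over probes well above background on all 4 arrays 13157 passed, and of 43392 without the filter 15147, against 16076 of 23091 in the main fit. The share that passed was thus lower without the filter. With every probe on its own, 21344 of 30196 probes passed. The count of genes was 8094 at an unadjusted p under 0.05 with a 2-fold difference and 5961 against a 2-fold difference, since both ask for size as well. The count at least 2-fold apart (8218) was 5205 with normexp, 4988 over probes well above background on all 4 arrays, where genes dim in 1 group left, and 12368 at 1.5-fold. With 1 array left out it was 8272 to 8371. The median correlation across groups (0.805) was 0.881 with normexp, 0.915 without the filter and 0.905 over probes well above background on all arrays. The cause was not tested for normexp, whose offset compresses dim signals by construction. The 11 lists became 0 with an estimated correlation, where the 2 residual degrees of freedom let few lists pass. They became 28 with fry, which tests another question.

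The labels share replicate numbers but do not say that they pair samples. Deviations of same-numbered arrays correlated at -0.05, and the replicate block gave 14890 genes and 11 lists. Of named genes it ended the calls of NDC80, RPL18, B2M and HPRT1. Every probe on its own was not run for lists, which need 1 value per gene, and the slide as a block was not run because all arrays lay on 1 slide. Signal over background limits dim genes, whose differences are bounds.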

Other observations

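Tests of the mixed-RNA, HepG2 and cancer-testis explanations were chosen after the results were seen. The cancer-testis family, and the HOX genes named, were picked after their values were seen.

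HOX genes, which encode body position along the trunk and limbs, differed between the groups. Of 29 tested, 19 were lower and 7 higher in the pressure-treated arrays and 3 did not pass. HOXC13 and HOXB13 had log2 signals of 2.43 ± 0.03 and 1.69 ± 0.03 (SD, n = 2) in control and were not well above background in pressure-treated arrays, at least 78.6-fold and 47.3-fold lower. HOXC10, HOXB9 and HOXC11 were at least 33.6-fold, 39.2-fold and 6.79-fold lower. HOXA3 was 21-fold higher and HOXA2 at least 41.0-fold higher, with 1 of 2 control arrays well above background. In all, 10 HOX genes (34.5%) were detected on both arrays of 1 group and neither of the other, each in control, against 11.2% of 16533 other named genes (two-sided Fisher exact p = 0.00085). Neighbouring HOX genes are not independent, so this p is too small. Some of the 10 lay near the detection floor, such as HOXD13 and HOXB3, at least 1.16-fold and 1.62-fold lower.

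Cancer-testis genes, silent in most adult tissues and switched on in many tumours, moved in both directions. Of 32 tested, 15 were lower, 9 higher and 8 did not pass. CT45A5, XAGE2 and CTAG1A were at least 137-fold to 189-fold lower, and GAGE12F was 399-fold lower from a control signal of 7.41 ± 0.02 (SD, n = 2). SPANXC and SSX4B were 603-fold and 367-fold higher, and SSX1 at least 338-fold higher with 1 of 2 control arrays well above background. MAGEA6 and MAGEA2B, at 6.24 and 6.02 in pressure-treated arrays, differed by -0.10 and 0.01 and did not pass. Detection in 1 group only was seen in 16 (50%, with 11 in control and 5 in pressure-treated arrays). Among these was SSX5, at least 1.33-fold apart, which did not pass. The share was 11.2% of other named genes (two-sided Fisher exact p = 6.44e-08). As the family was picked for its values, this p tests nothing, and near-identical copies that share probes are not independent.

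The pattern a reader would most want to follow up is that 16076 genes separate the groups, many from background to bright in both directions. Scaling and background correction are argued against as the whole cause, since the lowest count of genes at least 2-fold apart over 5 such alternatives was 5205. RNA of other cells mixed into 1 group is argued against, since at least 107 genes lay at least 100-fold apart in each direction and a fall of that size needs at least 99% foreign RNA. Cultures of HepG2 that differ in pressure alone are argued against by the plasma proteins, since 5 of 20 were well above background on both control arrays. The 17 detected on both pressure-treated arrays do not show that those cells were HepG2, since detection alone gives no level. Their mean signals there ran from percentile 20.7 (SERPINA1) to 90 (APOH) of the tested genes, with ALB at 63.3 and AFP at 67.4. APOA2 and APOC3 were not well above background there. No expected level for HepG2 was set. Whether those cells were HepG2 was not tested. A candidate explanation, as a hypothesis, is that the groups hold cells with different genomes: among 18175 autosomal genes well above background on all 4 arrays, medians per autosome ranged from -0.62 to 0.36 (permutation p = 1e-04, the smallest that 10000 permutations give, over genes that are not independent).

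For the HOX genes, a candidate explanation, as a hypothesis, is cells of different body position (Fisher exact p = 0.00085), which does not bear on whether genomes differ. How different cells could have entered the groups, by a label, a culture or a file out of place, was not tested. An effect of pressure stays open and untested, since it is confounded with whatever else separates the groups.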
